A study of Haloferax mediterranei with 16 samples.

How the data were processed

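Total RNA of Haloferax mediterranei cultures was labelled with Cy3 and Cy5 and hybridised to 16 custom two-colour Agilent arrays, 8 in each of 2 loops, per the labels. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. Loop 1 was extracted with a protocol for arrays without spike-in RNA and loop 2 with the standard two-colour protocol, and each loop occupied its own slide and scan day, per the file headers. Loop and slide can therefore not be told apart, and each contrast was made within a loop. The deposited files give the median intensity of each spot and of its local background in both dyes, the processed intensity after background subtraction and dye normalization by the scanner software, per the file headers, and a log10 ratio of red over green. The log10 ratio deposited by the authors equalled the log10 of the processed red over the processed green intensity within 0.0001 for 90.1% of spots and was exactly 0 for 9.93%.

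The direction of each ratio was taken from the authors' deposited targets table, which names the source in the green and the red channel of every array. On all 16 arrays this table opposes the dyes listed beside the source names in the labels. On the 8 arrays of loop 1 it matches the growth condition field of the same channels, and on 2 of the 8 arrays of loop 2. The plan fixed before the data were examined had taken the dyes beside the source names, and it was replaced before any ratio was computed, so the direction differs from the plan. The choice was then tested on intensities, which do not depend on the dyes: contrasts from differences in mean log intensity between arrays correlated with the ratio contrasts across identifiers with r from 0.55 to 0.79 in loop 1 and from -0.08 to 0.52 in loop 2. By rank, Spearman's rho ranged from 0.39 to 0.76 in loop 1 and from -0.25 to 0.50 in loop 2. Both values for Gln minus Asp lay below 0 (-0.04 and -0.25). Over the 88 identifiers with any difference in loop 2, a test added after the first result was seen, r lay between 0.73 and 0.88.

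In R 4.3.3 with limma 3.58.1, the median signals were corrected with normexp (offset 50) and each array was normalized by loess, with control spots at weight 0. Mean signals were planned, and median signals were used because the columns read here hold them. Spots marked as outliers, 0.94% of gene spots, were left out, spots of one probe were averaged, and the probes of one identifier were averaged (3 probes for 3901 identifiers, 1 for 50). Identifiers well above background in at least 4 of the 16 channels of a loop were kept, 3946 in loop 1 and 3945 in loop 2. A linear model with the source names and a gene-wise dye term was fitted per loop with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg per contrast, with a threshold of 0.05. The dye term was called for 6 identifiers in loop 1 and 3 in loop 2. A test over all source names called 151 identifiers in loop 1 and 88 in loop 2. No 2 arrays held identical values. The culture labels differ on every channel, so there is no pairing of cultures.

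Named identifiers are the 2 with the highest and the 2 with the lowest log2 fold change among those called and well above background in all 4 channels of the higher source name. The rule fixed before the data were examined took 5 and 5 per contrast of loop 1 and 3 and 3 per contrast of loop 2, and required gene names and gene lists. None of the 3951 identifiers matched the table of 3953 RefSeq genes (assembly of another naming system), and the files used here do not pair identifiers with names, so the product names, the gene lists and their set tests could not be applied. In loop 2 only identifiers already named in loop 1 are printed, a restriction chosen after the values were seen. Levels are log2 channel values after loess and quantile adjustment of mean intensities. Where an identifier was not well above background in any channel of the lower source name, the fold is an estimated lower bound, printed as "at least". It sets the mean of the brighter source name against the mean of, per array, the higher of its own level and the lowest level among spots well above background. The bound has no SE and is not guaranteed, since the limit of a single spot can lie above that lowest level.

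The fit was tested on simulated log ratios with the spread of the real identifiers and 200 changed identifiers. The noise was independent between identifiers, while in the real data identifiers with consecutive numbers moved together. The false calls below therefore need not hold for the real data. For NI minus AX over 3946 identifiers it called 30% of those changed by 1 on the log2 scale, 76% of those changed by 2, 98% of those changed by 4 and 100% of those changed by 6, with 12 false calls. For Glu minus Asp over 3945 identifiers the shares were 48%, 82%, 100% and 100%, with 4 false calls.

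The alternatives were no background correction, processed signals with median centring, median centring in place of loess, Aquantile after loess, no filter and a stricter filter (12 of 16 channels), no dye term, the brightest probe, both loops in one fit, an added fold threshold (log2 of at least 1), conditions from the growth condition field on all 16 arrays, and each array left out in turn. Array weights and a fit without the 2 arrays of largest residual spread in each loop were added after the data had been examined, as were the contrast on ammonium, the groups by contig, a separate dye term for 4 arrays of loop 1, and the readings of loop 2 with its dyes turned and with channels from the growth condition field.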

Results

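Transcript levels of Haloferax mediterranei, a halophilic archaeon that can use nitrate or ammonium as its nitrogen source, were measured on 16 two-colour Agilent arrays arranged as 2 loops of 8 arrays. In a loop, each array holds RNA of 2 source names, one per dye, and every pair of neighbours was hybridised in both dye orientations. Loop 1 carried the source names NI, HA, AE and AX, and loop 2 carried Glu, Gln, Asn and Asp. Each loop held 16 different culture labels, so each source name was measured in 4 cultures, each hybridised once. Cells were grown in a 25% (w/v) salt mixture with 10 g/l glucose and 40 mM of the nitrogen source, and starved cells spent 48 h without nitrogen. By elimination over the pairs on the arrays, where 1 of the 24 possible matchings fits all arrays of loop 1, NI is growth on nitrate, HA is nitrogen starvation, AE is ammonium in stationary phase and AX is ammonium in exponential phase. In loop 2, too, 1 of the 24 matchings fits the pairs that the growth condition field lists. This field repeats that of loop 1 array by array, and its reading is tested below. What the source names of loop 2 stand for is therefore left open. Each array carried 15744 spots, of which 15208 were gene spots for 3951 identifiers. Most of these identifiers consist of a contig number and a running number, while 50 start with hfx_c and 1 is bgah. The files used here do not pair the identifiers with gene names. Identifiers are therefore given as the array lists them, with at most 2 that rose and 2 that fell per comparison.

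The signal over background differed between source names. In the nitrate channels (NI), 33.9% ± 8.21 of the gene spots were well above background (SD, n = 4), against 91.3% ± 9.67 in the starvation channels (HA), 79.5% ± 26.5 in AE and 87.6% ± 14.2 in AX. The median gene spot was between 1.34 and 2.84 times as bright as the median negative control in the 4 NI channels and between 6.76 and 48.2 times as bright in the 4 HA channels. In loop 2 the shares were 52.3% ± 18.2 for Glu, 98.4% ± 1.78 for Gln, 78.6% ± 39.8 for Asn and 65.2% ± 20.5 for Asp (SD, n = 4 each). These shares rest on the dyes of the deposited targets table. With the dyes of loop 2 turned they would be 74.6% ± 28.2 for Glu, 49.5% ± 35.9 for Gln, 89.0% ± 15.1 for Asn and 81.5% ± 20.02 for Asp. No gene spot was marked as saturated. The number of arrays limits the precision of all contrasts: each loop left 4 residual degrees of freedom.

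**Figure D1:**
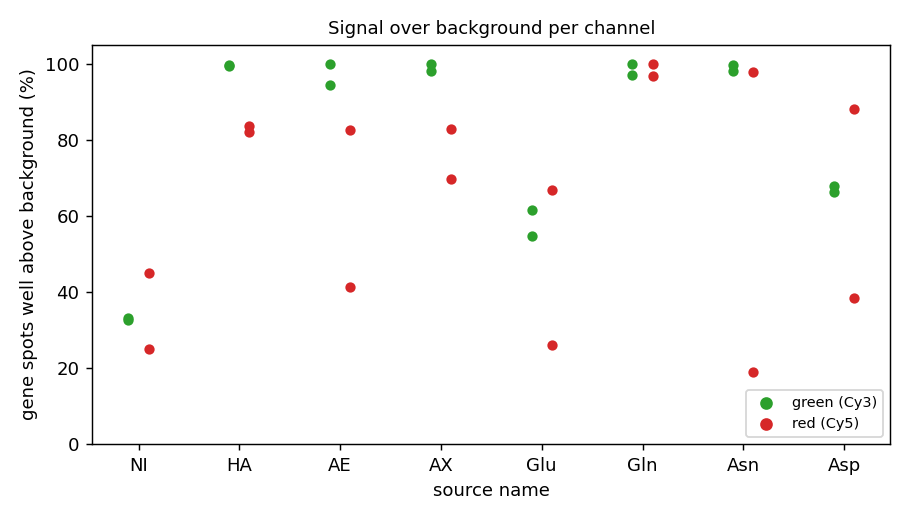
Percent of gene spots well above background (y axis) in each channel, by source name (x axis), with green points for Cy3 and red points for Cy5 and 4 channels per source name. The 4 NI channels lie between 25.0% and 44.9%, and the 4 Gln channels lie between 96.7% and 100%, or between 19.0% and 98.1% with the dyes of loop 2 turned.

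The first comparison asked which transcripts differ between growth on nitrate and exponential growth on ammonium. The identifier ctg2_01765 rose by 5.72 ± 0.53 (log2, SE) in NI over AX, a 52.8-fold difference with an adjusted p of 0.00838 in limma, and ctg2_01764 rose by 4.82 ± 0.70 (adjusted p = 0.0264). With each of the 8 arrays left out in turn, the call of ctg2_01765 was kept 7 times and that of ctg2_01764 only 2 times. All signed values take the dyes from the deposited targets table, and each would turn sign under the dyes given beside the source names in the labels. In loop 1 the growth condition field goes with the table on 8 of 8 arrays. The level of ctg2_01765 was 17.09 ± 1.09 in NI and 11.09 ± 0.47 in AX (log2, SD, n = 4 each). Among those called lower were ctg2_02318 (adjusted p = 0.00195) and ctg2_02317c (adjusted p = 0.00318). Neither was well above background in any NI channel, and by the estimated bound described above they were at least 22.3-fold and at least 7.93-fold lower in NI. Of 3946 identifiers tested, 102 changed, with 39 higher and 63 lower in NI, and all 3 probes had the same sign for each of the 102. Beside these counts stands the low signal over background of the NI channels: 14 of the 102 were not well above background in any of them. Leaving out any of the 8 arrays moved the count by over 1.5 times, from 0 without replicate 2 of the NI/AX arrays to 202 without replicate 2 of the HA/AE arrays. The excess of lower calls was not stable either, with 10 higher and 5 lower without replicate 1 of HA/AE and 7 and 6 without replicate 2 of NI/HA.

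The second comparison set nitrogen starvation against exponential growth on ammonium. Here ctg2_01765 rose by 5.36 ± 0.62 (log2, SE; 41.2-fold) and ctg2_02146 rose by 5.33 ± 0.58 (40.3-fold), both with an adjusted p of 0.0183 in limma, and with 1 array left out these calls were kept 4 and 5 of 8 times. The level of ctg2_02146 was 16.78 ± 0.51 in HA and 11.27 ± 0.55 in AX (log2, SD, n = 4 each). The identifiers ctg2_02318 and ctg2_02317c had the lowest values, at -6.03 ± 0.40 (adjusted p = 0.0049) and -4.81 ± 0.40 (adjusted p = 0.00779). In all, 259 identifiers changed, 84 higher and 175 lower in starved cells. A single stretch of 24 consecutively numbered identifiers, singled out after its values were seen, held 23 of those that fell, with a median of -3.44 and a range from -4.01 to -0.78. The same 24 had a median of -1.65 in NI minus AX, where 1 passed the threshold, and of -2.12 in AE minus AX, where none did. The growth condition field names a growth phase for AE and AX but not for NI or HA. In the contrasts of NI or HA with AE or AX, nitrogen source and growth phase can therefore not be told apart. No array held HA and AX together, so HA minus AX rests on the whole loop. The count was 194 without replicate 2 of HA/AE, 213 without replicate 1 of NI/AX, and moved by over 1.5 times without each of the other 6 arrays, down to 0 without replicate 2 of AE/AX. Without replicate 1 of NI/HA 18 were higher and 14 lower.

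**Figure D2:**
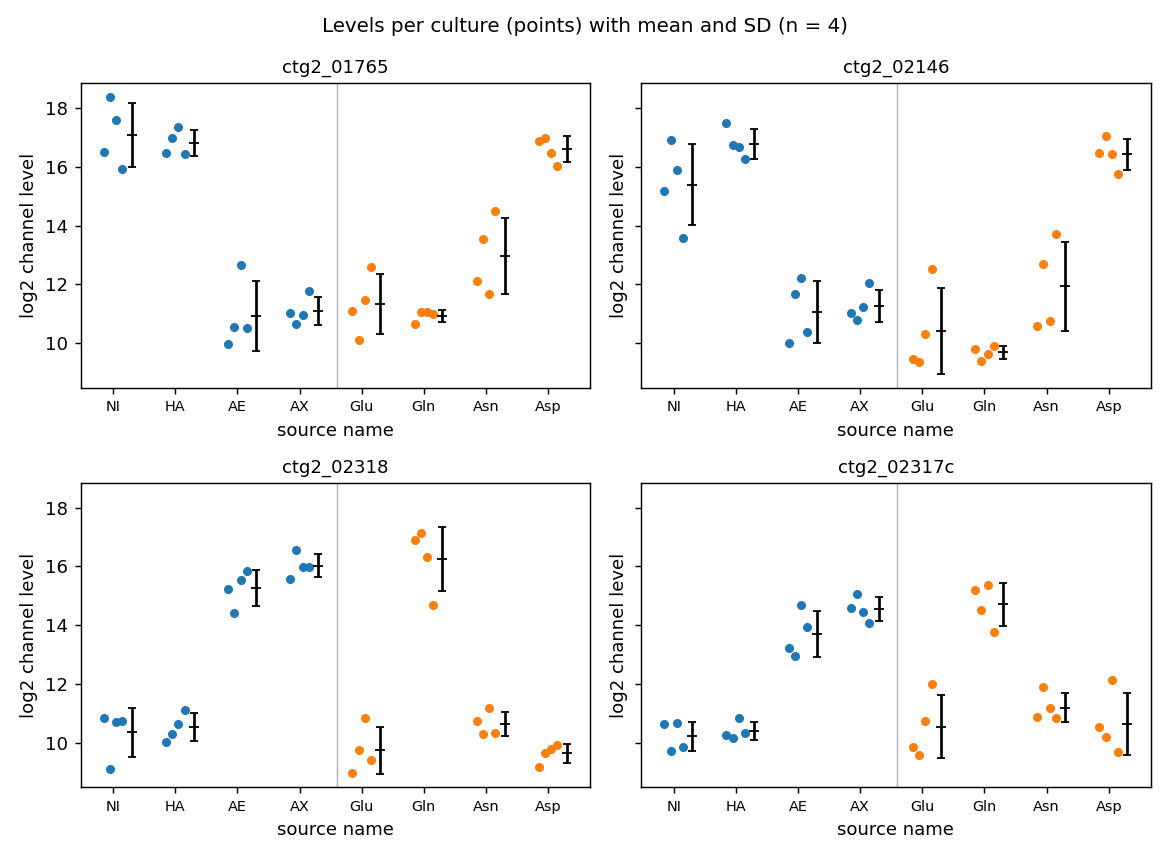
Log2 channel levels (y axis, after loess and quantile adjustment of mean intensities) of 4 identifiers in each of the 8 source names (x axis). Points are cultures, horizontal marks and bars are the mean and SD of 4 cultures, blue is loop 1 and orange is loop 2. The level of ctg2_02318 was 16.03 in AX, 15.26 in AE and 16.26 in Gln, and between 9.64 and 10.64 in the other 5 source names. With the dyes of loop 2 turned it would be 10.44 in Gln, 13.20 in Glu, 12.70 in Asn and 9.95 in Asp.

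Starvation and nitrate growth were next compared directly. The identifier ctg3_00338c rose in HA over NI by 4.16 ± 0.36 (log2, SE; 17.8-fold, adjusted p = 0.00789 in limma), and ctg2_00207c was higher as well (adjusted p = 0.0138). The former was well above background in 3 of the 4 NI channels. As ctg2_00207c was not well above background in any NI channel, it was at least 7.03-fold higher in HA. The identifiers ctg3_00100c and ctg2_01537c had the lowest values, at -4.32 ± 0.32 (adjusted p = 0.00352) and -3.92 ± 0.24 (adjusted p = 0.00174). The level of ctg3_00100c was 12.74 ± 0.99 in HA and 16.51 ± 0.34 in NI, and it was 16.11 ± 0.86 in AX (log2, SD, n = 4 each). The level of ctg2_01537c was 17.65 ± 0.66 in NI and 14.10 ± 1.70 in HA, and it was 14.50 ± 1.56 in AX. Over all identifiers, 130 changed, 39 higher and 91 lower in starved cells. Of these, 20 were lower in HA than in both NI and AX, 19 were higher in HA than in both, 13 were lower in HA than in NI and higher in NI than in AX, and 8 were higher in HA than in NI and lower in NI than in AX. The count was 146 without replicate 2 of HA/AE, 89 without replicate 1 of NI/AX, and moved by over 1.5 times without each of the other 6 arrays, down to 3 without replicate 1 of NI/HA.

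Some identifiers were called in both NI minus AX and HA minus AX. There were 19 identifiers higher in both than in AX, against 0.83 for independent lists of these sizes, and 37 lower in both, against 2.79. None was called in opposite directions. Both contrasts draw on the AX cultures, so the lists are not independent. Across identifiers, which are not independent replicates, the log2 fold changes correlated with r = 0.61, against 0.57 in 100 simulations of unchanged groups in the same design, and their covariance was 0.41, against 0.13. The share of identifiers with the same sign was 68.3%, against 69.5% in the simulations. The direct NI/AX arrays and the direct HA/AE arrays share no culture, and between them r was 0.12, with a Spearman rho of -0.09 and the same sign for 44.8% of identifiers. The HA/AE arrays set HA against AE in place of AX, so these 3 values do not measure the same relation as the overlap. In the same simulations a mean of 0.01 identifiers was called in both. The simulations hold no changed identifiers, so they do not show how much of the overlap comes from the shared AX cultures, which was not tested. Leaving out any of the 8 arrays moved the number higher in both by over 1.5 times, from 0 without replicate 2 of NI/HA to 35 without replicate 2 of HA/AE. The number lower in both was 43 without replicate 2 of HA/AE and at most 4 without any other array.

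**Figure D3:**
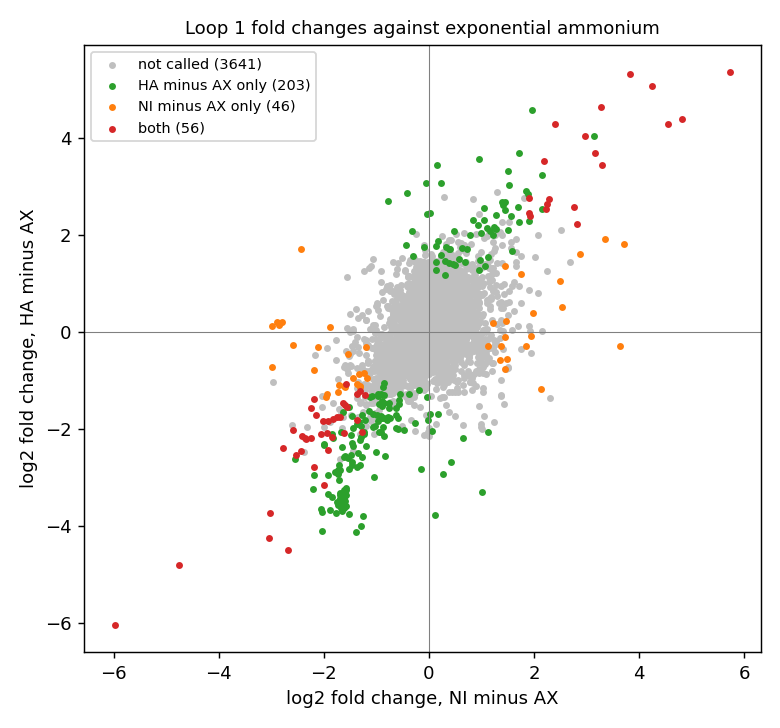
Log2 fold change of NI minus AX (x axis) against HA minus AX (y axis) for the 3946 identifiers of loop 1, coloured by which contrast passed an adjusted p of 0.05. The 56 identifiers called in both lie in the quadrants where both values have the same sign.

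The mean of the 2 conditions without ammonium (NI and HA) was also set against the mean of the 2 with ammonium (AE and AX), a contrast chosen after the data had been examined. Here 26 identifiers changed, 18 higher and 8 lower without ammonium. The identifier ctg2_01765 rose by 5.66 ± 0.44 (log2, SE; adjusted p = 0.00454 in limma) and ctg2_02146 by 4.61 ± 0.41 (adjusted p = 0.00684). Those lowest were ctg2_02318 (adjusted p = 0.000849) and ctg2_02317c (adjusted p = 0.0026), whose size is not given because neither was well above background in any NI channel. Of the 26, 12 of those that rose and 7 of those that fell were also called in the same direction in both NI minus AX and HA minus AX. The contrast is built from these same contrasts in the same fit, so shared calls and directions are partly built in. The count was 2 without replicate 1 of HA/AE, 68 without replicate 2 of HA/AE, 8 without replicate 1 of NI/AX and 11 without replicate 2 of NI/AX.

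Some of the identifiers at the top of the contrasts with AX lay in stretches of neighbouring numbers. A stretch of 4 that holds ctg2_01765 rose as a whole in NI over AX (log2 from 2.98 to 5.72) and in HA over AX (4.05 to 5.36). A stretch of 5 that holds ctg2_02146 rose as a whole in both as well (2.39 to 4.24 in NI, 3.70 to 5.33 in HA). A stretch of 4 that holds ctg2_02318 and ctg2_02317c fell as a whole in both, with a median of -3.45 in HA. These stretches were singled out after their values were seen. Over all 3880 pairs of consecutive numbers in loop 1, the log2 fold changes of HA minus AX correlated with r = 0.67, while the highest r after shuffling the identifiers within contigs was 0.089. That gave a one-sided permutation p of 0.000999, the smallest that 1000 shuffles can give, and all 6 contrasts of loop 1 reached it. Of these pairs, 117 were both called in the same direction in HA minus AX, against a mean of 10.1 after shuffling.

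Stationary and exponential growth on ammonium were compared on their own arrays and through the loop. No identifier passed an adjusted p of 0.05 in AE minus AX in limma. The smallest adjusted p was 0.0657, and 735 of the 3946 identifiers had an unadjusted p under 0.05. For ctg2_02318 the value was -1.01 ± 0.35 (log2, SE; adjusted p = 0.198), and for ctg2_01765 it was -0.24 ± 0.53 (adjusted p = 0.798). The count was 18 (2 higher, 16 lower) without replicate 1 of HA/AE and stayed at 0 when any of the other 7 arrays was left out. It was 55 (1 higher, 54 lower) with a stricter filter on dim identifiers, 6 (all lower) without a dye term and 186 (14 higher, 172 lower) in one fit of both loops. Without the 2 arrays of largest residual spread, a setting chosen after the data had been examined, it was 673 (416 higher, 257 lower). These arrays were picked by their residuals in the same fit, and leaving them out tends to lower the residual spread. The 673 calls are therefore no support for a difference.

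Against stationary ammonium cultures, 23 identifiers changed in starved cells, 19 higher and 4 lower. The highest were ctg2_01765 at 5.61 ± 0.53 (log2, SE; adjusted p = 0.00718 in limma) and ctg2_02146 at 5.41 ± 0.50 (adjusted p = 0.00707). The lowest were ctg2_02318 at -5.03 ± 0.35 (adjusted p = 0.00334) and ctg2_02317c at -3.72 ± 0.35 (adjusted p = 0.00707). In NI minus AE 4 identifiers changed. Those higher were ctg2_01765 at 5.96 ± 0.62 (adjusted p = 0.033) and ctg2_01537c at 3.35 ± 0.27 (adjusted p = 0.00962). Those lower were ctg2_02318, at least 13.1-fold (adjusted p = 0.00962), and ctg2_02317c, at least 4.43-fold (adjusted p = 0.0357). Leaving out replicate 1 of HA/AE left 0 calls in HA minus AE, and each removal other than that of replicate 2 of HA/AE (21) or replicate 1 of NI/AX (22) moved the count by over 1.5 times. For NI minus AE, each removal other than that of replicate 1 of NI/AX (6) did, with 24 without replicate 2 of HA/AE, 1 without replicate 1 of NI/HA and 0 without the others. The calls in NI minus AE were kept 2 of 8 times, or 3 for ctg2_02318.

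Whole groups of identifiers, taken by the contig number in their prefix, also shifted, as was seen after the data had been examined. Among identifiers with a value on all 8 arrays, in AE minus AX the 438 identifiers of contig 3 had a median of 0.65 and the 265 of contig 4 a median of 0.59, while the median of the 3051 of contig 2 was -0.09 (log2). Limma's camera test with its preset correlation gave adjusted p-values of 6.39e-11 and 6.53e-09 for contigs 3 and 4, over 24 tests in the loop. With an estimated correlation the adjusted p-values were 0.543 and 0.629. Measured array by array against contig 2, contig 3 gave 1.12 for AE minus AX on one AE/AX array and -1.32 for AX minus AE on the other, where the dyes were exchanged. The exact two-sided relabelling test of the loop estimate, 0.74 for contig 3, gave p = 0.464, and that for contig 4, 0.71, gave p = 0.488, both with an adjusted p of 0.732 over 18 relations. Relabellings that exchange both AE/AX arrays together keep the size of the difference seen on them, so a large p says little here. No identifier of either contig was called in this contrast. Measured against the median of all other identifiers, the shifts were 0.69 and 0.61. They were 0.38 and 0.37 without replicate 1 of AE/AX, and 0.33 and 0.25 without replicate 2 of AE/AX. With conditions from the growth condition field on all 16 arrays they were 0.19 and 0.25. That setting adds the 8 arrays of loop 2 as if they held these conditions, while the reading of the loop 1 arrays stays the same.

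**Figure D4:**
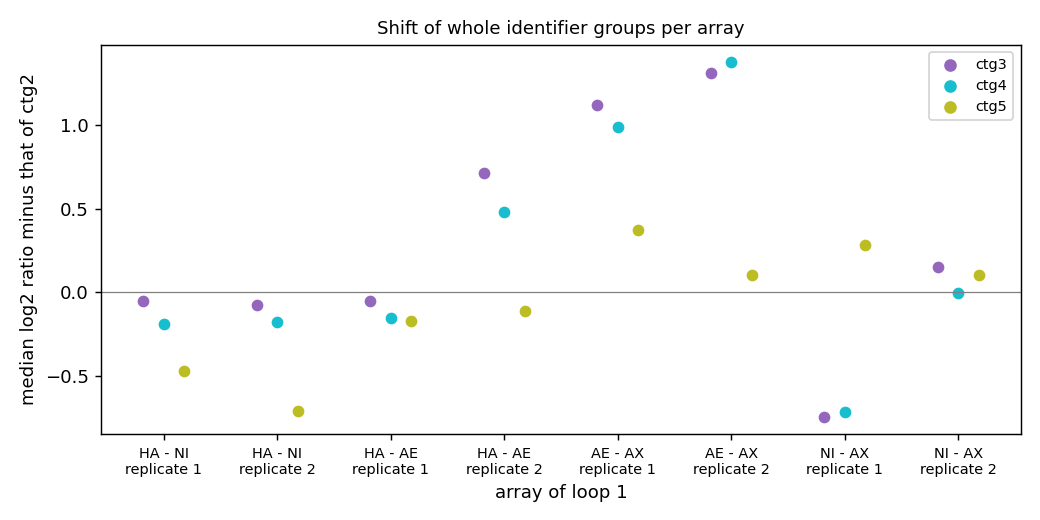
Median log2 ratio of the identifiers of contigs 3, 4 and 5 minus that of contig 2 (y axis) on each array of loop 1 (x axis), turned so that the first-named source name is the numerator. Contigs 3 and 4 lie above 0 on both AE/AX arrays and on opposite sides of 0 on the 2 arrays of HA/AE.

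Some of the identifiers that led the loop 1 contrasts also differed between source names in loop 2, while ctg3_00100c and ctg2_00207c passed no contrast there (smallest adjusted p 0.296 and 0.0576). The direction in loop 2 is likely rather than settled and rests on the deposited targets table. The growth condition field matches that table on 2 of the 8 arrays of this loop, but it repeats the field of loop 1. Over the 88 identifiers with any difference, intensity differences between arrays went with the table (r from 0.73 to 0.88). Over all identifiers they decided nothing, and by rank both values for Gln minus Asp went against the table (Spearman rho of -0.04 and -0.25). Whatever the dyes, ctg2_02318 reached at least 14.69 in 1 channel of each array with Gln, and at most 10.32 on the other arrays. These values argue against turned dyes for the identifiers they cover. Signs, levels and bounds in loop 2 all depend on the direction. The identifier ctg2_02318 was high in Gln, with a level of 16.26 ± 1.10 (log2, SD, n = 4), and was not well above background in any Glu or Asp channel. It was at least 39.0-fold lower in Glu than in Gln (adjusted p = 0.000693 in limma) and at least 50.01-fold lower in Asp than in Gln (adjusted p = 0.00189). With the dyes of loop 2 turned, its level would lie between 8.97 and 11.20 in Gln and would be 13.20 ± 3.93 in Glu and 12.70 ± 3.85 in Asn (log2, SD, n = 4 each), and these bounds would not hold. In Gln minus Asn its value was 5.13 ± 0.44 (log2, SE; adjusted p = 0.00503), and it was well above background in 3 of the 4 Asn channels. The identifier ctg2_02146 was high in Asp, at 16.43 ± 0.53 (log2, SD, n = 4), while with the dyes turned it would be 12.06 ± 1.88 in Asp, 13.07 ± 3.90 in Glu and 13.05 ± 3.93 in Asn. It rose by 5.14 ± 0.33 in Asp over Glu (log2, SE; adjusted p = 0.000459), and its value was -4.97 ± 0.38 in Gln minus Asp (adjusted p = 0.00189) and -3.60 ± 0.33 in Asn minus Asp (adjusted p = 0.00863). It was well above background in 1 of the 4 Glu channels and 3 of the 4 Asn channels. The stretch of 5 with ctg2_02146 and the stretch of 4 with ctg2_01765 both rose as a whole in Asp over Glu. The identifier ctg3_00338c was higher in Glu than in Asp by 2.30 on the log2 scale, its value in Asp minus Glu being -2.30 ± 0.27 (adjusted p = 0.00969), and higher in Glu than in Asn by 2.57 ± 0.31 (adjusted p = 0.0376), a call kept 2 of 8 times with 1 array left out.

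Of 3945 identifiers tested in loop 2, 15 changed in Glu minus Gln (13 higher, 2 lower), 1 in Gln minus Asn, which was ctg2_02318, and 371 in Asn minus Asp (175 higher, 196 lower). In Asp minus Glu 16 changed (15 higher, 1 lower), in Glu minus Asn 4 (all higher) and in Gln minus Asp 9 (2 higher, 7 lower). The count for Asn minus Asp depended on the processing: it was 15 (8 higher, 7 lower) without background correction, 1 with the scanner software's processed signals and median centring, which changes more than the background, and 440 (283 higher, 157 lower) with the brightest probe. It was 0 without replicate 2 of Asn/Asp, 1056 (565 higher, 491 lower) without replicate 1 of Gln/Asn and moved by over 1.5 times without each of the other 6 arrays. Without replicate 2 of Asp/Glu the counts were 26 in Glu minus Gln, 289 in Gln minus Asn, 41 in Asp minus Glu, 85 in Glu minus Asn and 68 in Gln minus Asp. Without replicate 2 of Asn/Asp they were 6, 0, 8, 0 and 2 in the same order. In these 5 contrasts all removals moved a count by over 1.5 times except, for Glu minus Gln, those of the Gln/Asn arrays and replicate 1 of Asn/Asp and of Asp/Glu, for Gln minus Asn, those of replicate 2 of Glu/Gln and replicate 1 of Asn/Asp, for Asp minus Glu, those of the Glu/Gln arrays and replicate 1 of Gln/Asn and of Asn/Asp, and for Gln minus Asp, that of replicate 2 of Gln/Asn. With median centring in place of loess the splits were 251 higher and 523 lower in Asn minus Asp, 91 and 95 in Gln minus Asn, 4 and 2 in Glu minus Gln, and 2 and 15 in Gln minus Asp. Without background correction they were 3 and 1 in Glu minus Asn and 1 and 0 in Gln minus Asp.

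The growth condition field of loop 2 repeats that of loop 1 array by array, which would make Glu nitrate, Gln starvation, Asn stationary ammonium and Asp exponential ammonium. Under this reading the 6 contrasts of loop 2 had a mean correlation of 0.000699 with those of loop 1 across 3941 identifiers. Among the 24 possible assignments of source names to conditions it ranked 14, which gives an exact one-sided p of 0.583. The highest mean correlation of any assignment was 0.20. With the dyes of loop 2 turned it ranked 11, where the highest was 0.30, and with each channel taken from the growth condition field it ranked 14, where the highest was 0.34. The single correlations under this reading ranged from -0.18 for starvation against exponential ammonium to 0.33 for stationary against exponential ammonium.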

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

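The tests in this part were chosen after the results were seen, as were the 9 identifiers whose levels enter them. Among 82 groups of 4 to 8 values (percent of spots well above background, residual spread of arrays, and levels of these identifiers) examined for a sample far from the others, 4 stood out, where chance alone gives about 1 in 20. In the Asn channel of replicate 1 of the Gln/Asn arrays, 19.0% of gene spots were well above background, while the other 3 Asn channels lay between 97.8% and 99.7%. The log2 level of ctg2_02318 in NI was 9.12 on replicate 1 of the NI/AX arrays, against 10.69 to 10.85 in the other 3 cultures, where none of the 4 was well above background, so these are no measured levels. The log2 level of ctg3_00100c in AX was 14.83 on replicate 2 of the NI/AX arrays, against 16.47 to 16.63, and its level in Asp was 17.25 on replicate 1 of the Asn/Asp arrays, against 15.88 to 16.05. The values for Asn and Asp rest on the dyes of the deposited targets table, and with the dyes of loop 2 turned neither would stand apart: the 19.0% would belong to Gln, whose channels would range up to 98.1%, and the 17.25 to Asn, whose levels would start at 14.42.

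If the source names of loop 2 are matched to conditions by the pairs that the growth condition field lists on each array, the same contrast exists in both loops. With the dyes of the deposited targets table, which that field matches on 2 of the 8 arrays, limma's test of the difference between loops called identifiers in each: 67 for NI minus AX against Glu minus Asp, 235 for HA minus AX against Gln minus Asp, 38 for AE minus AX against Asn minus Asp, 55 for HA minus NI against Gln minus Glu, 77 for HA minus AE against Gln minus Asn, and 30 for NI minus AE against Glu minus Asn.

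The arrays carry 200 control spots for E1A spike-in RNA, which no comparison used. At least 90% of them were well above background in 4 of the 16 channels of loop 1, although its extraction protocol is for arrays without spike-ins, and in 16 of the 16 channels of loop 2. The 4 channels are the Cy3 channels of the AE/AX and NI/AX arrays, which are all the arrays that hold AX. A separate dye term for these arrays was called for 0 identifiers. It left the log2 values unchanged for identifiers with a value on all 8 arrays. This was fixed by the design, since these arrays are complete dye-swapped pairs, so it tests nothing about the contrasts. Other differences of these arrays were not tested.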

How the results depend on the processing

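Array weights, the fit without 2 arrays per loop and the contrast on ammonium were chosen after the data had been examined. The 2 arrays left out in each loop were picked by their residuals in the same fit. That tends to lower the residual spread, so a rise in calls there is no support for a difference. The cause of each move below was not tested unless stated. Aquantile, which leaves ratios within arrays as they are, the absence of a filter and the fold threshold moved no count by over 1.5 times. With the stricter filter, which tests fewer identifiers, the counts were 170 for NI minus AX, 55 for AE minus AX, 12 for NI minus AE, 0 for Gln minus Asn and 72 for the ammonium contrast, and the identifiers shared by NI minus AX and HA minus AX were 32 higher and 57 lower. In one fit of both loops they were 266 for NI minus AX, 186 for AE minus AX, 310 for HA minus NI, 69 for HA minus AE, 21 for NI minus AE, 24 for Glu minus Gln, 58 for Gln minus Asn, 574 for Asn minus Asp, 52 for Glu minus Asn, 19 for Gln minus Asp and 124 for the ammonium contrast, with 43 higher and 96 lower shared. With conditions from the growth condition field on all 16 arrays they were 16 for NI minus AX (13 higher, 3 lower), 20 for HA minus AX (16 higher, 4 lower), 0 for HA minus NI, 1 for HA minus AE and 0 for NI minus AE, with 13 higher and 1 lower shared. With array weights they were 460 for NI minus AX, 482 for HA minus AX, 363 for HA minus NI, 64 for HA minus AE, 27 for Glu minus Gln, 250 for Gln minus Asn, 1373 for Asn minus Asp, 60 for Glu minus Asn, 24 for Gln minus Asp and 249 for the ammonium contrast, with 75 and 125 shared. Without the 2 arrays of largest residual spread in each loop they were 28 for NI minus AX, 82 for HA minus AX, 673 for AE minus AX, 12 for HA minus AE, 9 for NI minus AE, 35 for Glu minus Gln, 7 for Gln minus Asn, 1075 for Asn minus Asp, 10 for Glu minus Asn and 12 for the ammonium contrast, with 8 and 7 shared. With a separate dye term for the 4 arrays of loop 1 with E1A spots in Cy3, also chosen afterwards, which left 3 residual degrees of freedom, they were 56 for NI minus AX, 144 for HA minus AX, 0 for AE minus AX, 83 for HA minus NI, 13 for HA minus AE and 7 for NI minus AE. Without the dye term they were 6 for AE minus AX, 8 for NI minus AE, 215 for Asn minus Asp and 20 for Glu minus Asn. Median centring gave 0 for NI minus AE, 6 for Glu minus Gln, 186 for Gln minus Asn, 774 for Asn minus Asp, 0 for Glu minus Asn, 17 for Gln minus Asp and 24 shared lower. Without background correction there were 0 for Gln minus Asn, 15 for Asn minus Asp and 1 for Gln minus Asp, and with processed signals 2, 1 and 1, with 0 for Glu minus Asn. The brightest probe gave 30 for Gln minus Asn and 0 for Glu minus Asn.

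With 1 array left out, the counts ranged from 0 to 202 for NI minus AX, 0 to 213 for HA minus AX, 0 to 18 for AE minus AX, 3 to 146 for HA minus NI, 0 to 22 for HA minus AE, 0 to 24 for NI minus AE, 3 to 26 for Glu minus Gln, 0 to 289 for Gln minus Asn, 0 to 1056 for Asn minus Asp, 1 to 41 for Asp minus Glu, 0 to 85 for Glu minus Asn, 2 to 68 for Gln minus Asp and 2 to 68 for the ammonium contrast, and those shared by NI minus AX and HA minus AX from 0 to 35 (higher) and 0 to 43 (lower). The 38 values of single identifiers kept their direction in every setting run for them. Conditions from the growth condition field were run for the values of loop 1 only. Turned dyes, which would turn each sign, were not among the settings. Their call was kept in 378 of 433 values under other settings and in 196 of 304 with 1 array left out. The shift of contig 3 in AE minus AX was above 0 in every setting, between 0.33 and 0.95 with 1 array left out, and that of contig 4 between 0.25 and 0.84. With conditions from the growth condition field on all 16 arrays, which adds loop 2 to the fit, they were 0.19 and 0.25.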

Other observations

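The tests in this part, except the test of the loop 2 conditions and that of the dyes over all identifiers, were chosen after the results were seen. In HA minus NI the 120 identifiers of contig 5 had a median of -0.48 (log2), and 24.2% of them lay above 0. Limma's camera test gave an adjusted p of 8.76e-08 with the preset correlation and 0.543 with an estimated one, and the exact two-sided relabelling p was 0.264 (adjusted 0.732). In loop 2 contig 3 had a median of -0.31 in Gln minus Asn, with a camera adjusted p of 1.25e-08 and 0.142 with an estimated correlation. The exact two-sided relabelling p was 0.208 (adjusted 0.699), and the sign rests on the dyes of the deposited targets table. For both contrasts a large relabelling p says little, for the reason given for AE minus AX.

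The first pattern is that identifiers with consecutive numbers moved together, with r = 0.67 in HA minus AX. The tables argue against array layout, since identifiers on adjacent spots whose numbers are not near each other correlated with r = 0.0119, and against contig-wide shifts as the whole cause, since r was 0.657 after each contig's median was taken off. A candidate explanation is shared transcription of neighbours, if the suffix c marks the strand, which the sources used here do not say: pairs with the same suffix correlated more than pairs with different suffixes, by 0.209 (one-sided permutation p = 0.000999, the smallest that 1000 shuffles give, adjusted p = 0.00133 over 12 contrasts). Other values do not ask for an effect of the nitrogen source. Pairs with different suffixes still correlated at 0.53, and the dye term of loop 1, which compares no conditions, gave r = 0.408. In AE minus AX, where both have ammonium and the growth phase differs, r was 0.73. No identifier was called there, but its log2 values spread as widely as those of NI minus AX (SD 0.73 and 0.72). The r of AE minus AX therefore does not argue against shared transcription. A technical component or differences between cultures that neighbours share stay open.

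The second pattern is the shift of contigs 3 and 4 in AE minus AX. A trend with intensity is argued against, since the highest median among 10000 intensity-matched lists of other identifiers was 0.046 for contig 3 and 0.0919 for contig 4, against 0.65 and 0.59. Probes near background are argued against as the whole cause, since the shift was 0.649 and 0.412 among identifiers well above background in at least 12 of 16 channels. A spread between cultures unrelated to the condition stays open. Relabelling the channels within arrays gave exact two-sided p-values of 0.464 and 0.488. This test cannot decide it, since relabellings that exchange both AE/AX arrays together keep the size of the difference on them. No biological explanation was tested.

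The third pattern is that NI minus AX had 102 calls while the NI channels had the lowest signal over background. The median negative control lay between 821 and 6073.5 in the NI channels and between 48 and 863 in the AX channels. Of the 1235 identifiers well above background in every NI and AX channel 4.94% were called, against 1.51% of the other 2711. This split decides nothing, since an identifier that falls in NI can leave the first set by its fall. Among the 1235, 31 were higher and 30 lower in NI, and among the others 8 were higher and 33 lower. Low signal over background stays open as a cause of part of the calls.

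For the dyes, the lowest of 4 correlations between intensity differences and ratio contrasts was 0.554 in loop 1, which goes with the deposited targets table. In loop 2 the lowest was -0.0807 over all identifiers, which decides nothing, and 0.73 over the 88 with any difference, which goes with that table. The reading that the source names of loop 2 stand for the 4 conditions of loop 1 ranked 14 of 24 assignments with the dyes of that table, 11 with these dyes turned (added after the results were seen, as was the next) and 14 with each channel taken from the growth condition field. It came first in none of the 3, which argues against it as far as correlation with loop 1 can tell.

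The 2 channels of each array were also relabelled in 100 of 125 possible ways per loop, the real one included. The share of relabellings that called as many, taken singly, was 0.01 where the real one called the most: NI minus AX with 102 calls and at most 92 in another (1 of 100 as large), HA minus AX with 259 and 11 (1), the ammonium contrast with 26 and 19 (1), and Asn minus Asp with 371 and 221 (1). The share was also under 0.05, although another relabelling called more, for HA minus NI with 130 and 142 (2), HA minus AE with 23 and 45 (2), Glu minus Gln with 15 and 22 (2), Asp minus Glu with 16 and 17 (2), Gln minus Asp with 9 and 10 (2) and NI minus AE with 4 and more than 100 (4). Adjusted over the 13 results, the share was 0.0289 for all of these but NI minus AE, where it was 0.052. The share was above 0.05 for AE minus AX, with 0 calls and up to 328 in another relabelling (100), Gln minus Asn with 1 and 319 (14), and Glu minus Asn with 4 and 80 (6). Relabellings that called many times the real count, as for these 3 and for NI minus AE, could point to a structure of the cultures that the source names do not follow. A relabelling also carries differences between source names into other contrasts and into the residual spread, and the cause was not tested. For every result the median count of the other relabellings was 0. As a wrong relabelling can lower the calls in this way, a small share does not exclude chance.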
